A study of Homarus americanus with 36 samples.

How the data were processed

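Gene expression was measured in 36 larvae of the American lobster, Homarus americanus, on two-colour oligonucleotide arrays with 1 animal per array. Per the labels' protocols, larvae were exposed individually to endosulfan, an organochlorine insecticide, for 14 days from stage III, with fresh solution 3 times per week, and animals alive at the end were taken for total RNA. RNA of each animal carried Cy3. A pooled reference of 15 stage III and 15 stage IV animals carried Cy5 on every array. No dyes were swapped, so a dye effect that differs between probes cancels only in differences between groups.

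The deposited scanner files hold, per the file headers, spot intensities on a linear scale extracted with Agilent Feature Extraction 10.7.3.1; the submitters' processing notes list version 11. Their LogRatio column is, per the file headers, a log10 ratio of Cy5 over Cy3 after background subtraction and dye normalization. The deposited value table was set against the scanner values: each column equals the log2 ratio of processed Cy3 over processed Cy5 of its array to within 5e-06, on the log2 scale and not centred, with column medians from -0.32 to -0.02. Its scale and direction are therefore known, and every ratio here is animal over reference. Each array holds 14960 listed spots: 14592 lobster probes from 14575 contigs, 17 of which have 2 probes, and 368 spots of GFP, Alien and Buffer features. The remaining 416 positions of the 124 by 124 grid were not analysed here.

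The files do not pair the probe identifiers with genes. None of them matched a gene, transcript or protein identifier or a symbol among 27431 genes of the reference table of assembly GMGI_Hamer_2.0. Probes are therefore given by identifier, and the 24 gene lists written before the data were examined, the markers of cell types and the counts of 1 probe per gene name were not run. The naming rule written before the data were examined took the 12 largest rises and the 12 largest falls with a gene name. With no names, the 2 largest rises and the 2 largest falls of a comparison are given, among called probes with Cy3 well above background on at least 3 arrays of the brighter group.

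The values computed here started from the median spot intensities and median background intensities, since the mean intensities that the design foresaw are not among the columns used. Background was corrected with normexp at an offset of 50, and Cy5 and Cy3 were normalized within each array by loess, with control features at weight 0. No normalization between arrays was applied. Spots marked as non-uniform by the scanner software in either channel were left out of the loess curve and of the limma fits. They were a median of 24 of the lobster probes per array. Values of single animals, group means, SDs, correlations between arrays, principal components, scores and figures kept these spots. A probe was tested when Cy3 was well above background on at least 6 of the 36 arrays, which kept 12194 probes and left out 2398. The number of arrays limits the precision of every value: the median standard error of a difference from control was 0.104 on the log2 scale.

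Differences were tested with limma 3.58.1 in R 4.3.3, with the 6 groups fitted together on all 36 arrays, a constant prior variance, two-sided moderated tests and Benjamini-Hochberg adjustment within each comparison. Calls have an adjusted p under 0.05. The residual degrees of freedom were 30 and those of the prior 4.75. Each of the 5 concentrations was compared with control. Moderated F tests asked for any difference among the 6 groups and among the 5 groups of stage IV animals, a slope on the rank of concentration was fitted to the 30 stage IV arrays, and the 0.26 µg/L group was compared with the mean of the other 5 groups. Comparisons of 0.26 µg/L with each lower concentration were added after the data were examined.

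Where a called probe was not well above background in Cy3 on any array of a group, the difference is given as a lower bound. It sets the bright group's mean against the mean, over the dim group's arrays, of the higher of the lowest signal among probes well above background and the probe's own signal, in Cy3 after loess and Aquantile. Such bounds are open to dye bias.

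The file headers place the 36 arrays on 20 slides, 16 of which hold 2 of them, and on 9 scan days. Of the arrays, 19 lay at the top and 17 at the bottom of a slide. Among controls 5 of 6 lay at the top, and among 0.05 and 0.26 µg/L animals 2 of 6 each. Slide, scan day and position were tested as batches.

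The fits were tested on simulated data built from the probe means and residuals of these arrays, with 200 probes shifted at each of 3 sizes in the comparison of 0.05 µg/L with control over 12194 probes. With the residuals of whole arrays shuffled, 79.8% of shifts of 0.5, 97.6% of shifts of 1 and 99.8% of shifts of 2 on the log2 scale were recovered over 10 simulations, and 5.69% of the calls were false. Recovery is lower where fewer probes change, because the adjustment is then stricter.

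The alternatives changed the background correction, the normalization within and between arrays, the source of the values, the filter on dim probes, the treatment of non-uniform spots, the blocks and factors in the model, the arrays fitted, the array weights, the prior, the adjustment and the dose scale. Each array was also left out in turn.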

Results

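The study compared unexposed control larvae of the lobster with larvae exposed to 5 concentrations of endosulfan, an insecticide that blocks GABA-gated chloride channels, and asked how exposure affects gene expression. Each group held 6 separately housed animals: a control and 0.005, 0.008, 0.021, 0.05 and 0.26 µg/L. All 6 animals at 0.26 µg/L were labelled stage III and all 30 others stage IV. Stage III is the last larval stage of this species and stage IV the first after metamorphosis. Concentration and stage therefore cannot be told apart at 0.26 µg/L. Animals were taken only if they survived the exposure.

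In Cy3, the channel of the animals, 53.4% to 89.2% of the 14592 lobster probes were well above background on an array, with a median of 73.3%. The reference channel had 26.5% to 70.8%. Group means in Cy3 ranged from 68.9% ± 9.06 (SD, n = 6) in controls to 75.1% ± 8.80 (SD, n = 6) at 0.021 µg/L. Normalized log2 ratios of pairs of arrays correlated across probes between 0.36 and 0.90, with a median of 0.74 within groups and 0.71 between groups. Arrays of different groups on the same slide had a median of 0.80, above that within groups, and those of different groups on the same scan day 0.74. Probes are not independent replicates in these correlations. The median within-group SD of a probe lay between 0.156 in controls and 0.183 at 0.05 µg/L on the log2 scale. The first 2 principal components held 17.1% and 16.4% of the variance, of which groups accounted for 45.6% and 36.02% and scan days for 32.6% and 30.5%. Scan days accounted for 54.5% and 55.3% of the next 2 components. Chance raises such shares, more for 9 scan days than for 6 groups, and they were not set against permuted labels.

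**Figure D1:**
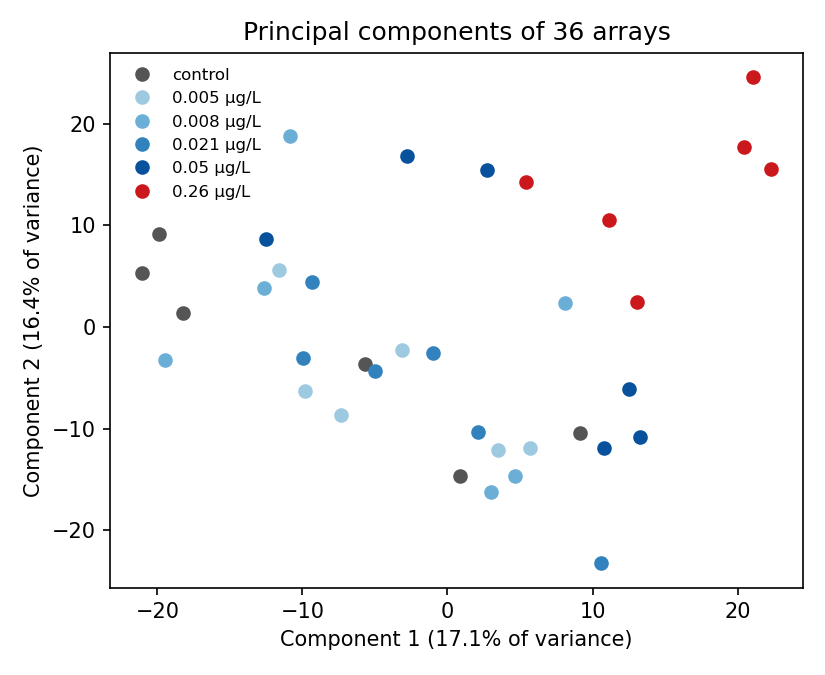
Scores of the 36 arrays on the first 2 principal components of the normalized log2 ratios, with 17.1% (x axis) and 16.4% (y axis) of the variance; each point is 1 animal, coloured by group. The 6 animals at 0.26 µg/L lie at the upper right.

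At 0.26 µg/L, 453 of 12194 probes differed from control, 238 higher and 215 lower. The falls were the larger changes. Among called probes, 77 fell by more than 1 on the log2 scale and 36 rose by more than 1, while 21 fell and 1 rose by more than 2. The median rise was 0.56 and the median fall -0.79. Probe HAZ17835_1 fell from a log2 ratio of 3.14 ± 0.50 (SD, n = 6) in controls and was not well above background in any of the 6 animals at 0.26 µg/L, which makes it at least 50.7-fold lower (limma adjusted p = 2.6e-06). HAZ08103_1 fell by 5.32 ± 0.78 (SE) on the log2 scale, from 3.22 ± 0.40 to -2.10 ± 1.58 (SD, n = 6 each), with limma adjusted p = 3.32e-05 and all 6 exposed animals below every control. HAZ15490_1 rose by 2.33 ± 0.32 (SE), or 5.02-fold, with limma adjusted p = 1.61e-05 and all 6 exposed animals above every control. HAZ03164_1 rose by 1.87 ± 0.47 (SE, limma adjusted p = 0.0157), with 4 of 6 animals above every control. Its call was lost without loess (adjusted p = 0.0909), with scan day as a fixed factor (0.122), without control replicate 6 (0.0557) and without 0.26 µg/L replicate 6 (0.0682).

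The 453 probes were measured mostly on bright spots: 413 were well above background on all 12 arrays compared. Counts depended on the normalization within arrays. Median centring in place of loess gave 91 probes, 26 higher, and the Cy3 channel alone gave 115, 34 higher, so the near balance of rises and falls did not hold there. With position on the slide in the model 346 probes were called, with slide as a random block 554, and with scan day as a random block 577. On the 3 scan days that held both groups, 99.3%, 99.8% and 95.6% of the 453 probes differed in the same direction, with median differences of 0.83, 0.78 and 0.51. These probes were called on arrays that include those of each day. Among probes called without the day, 157 of 160, 223 of 225 and 338 of 379 had the same direction on it.

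**Figure D2:**
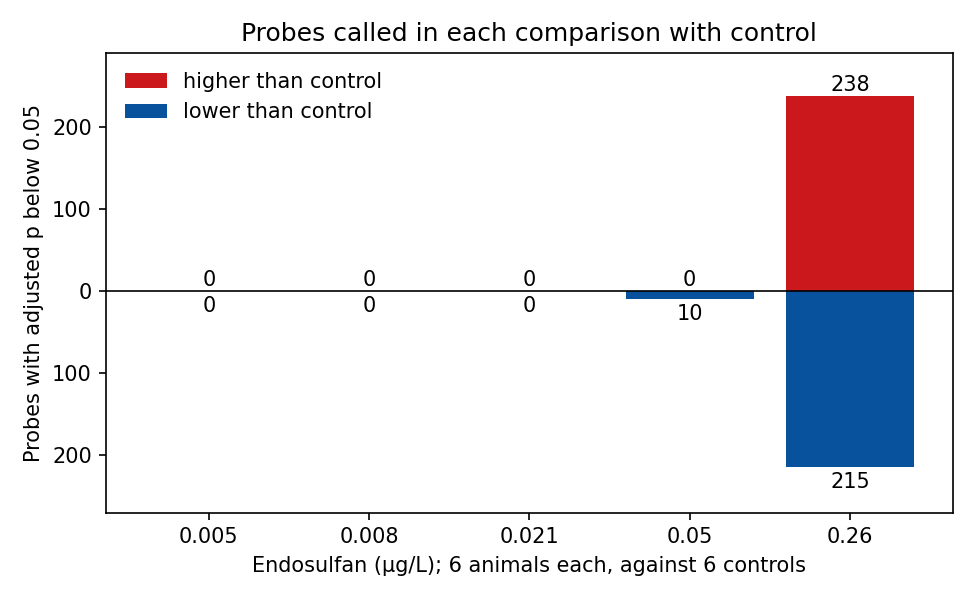
Number of probes with a limma adjusted p below 0.05 (y axis) that were higher (red, upward) or lower (blue, downward) than control at each endosulfan concentration (x axis, µg/L), with 6 animals per group. No probe was called at 0.005, 0.008 or 0.021 µg/L, 10 were lower at 0.05 µg/L, and 238 were higher and 215 lower at 0.26 µg/L.

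Against the mean of the 5 stage IV groups, 709 probes differed at 0.26 µg/L, 329 higher and 380 lower. Of 190 probes called in the Cy3 channel alone, 60 were higher, and median centring gave 180. Without 0.26 µg/L replicate 3 the count was 450. Compared with each lower concentration in turn, 402 probes differed from 0.005 µg/L, 272 from 0.008 µg/L, 452 from 0.021 µg/L and 140 from 0.05 µg/L. Of the 453 probes that differed from control, 84 also differed in the same direction from all 4 lower concentrations. The number that also differed from 0.05 µg/L was 102, and all 102 did so in the same direction.

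At 0.05 µg/L, 10 probes differed from control and all 10 were lower. Their falls ranged from -4.41 to -0.66 on the log2 scale, 4 of them beyond 3. HAZ00850_1 fell by 4.41 ± 0.82 (SE), from 3.95 ± 0.60 to -0.46 ± 0.76 (SD, n = 6 each), with limma adjusted p = 0.026. HAZ04125_1 fell by 4.22 ± 0.78 (SE), from 3.69 ± 0.82 to -0.54 ± 0.45 (SD, n = 6 each), with limma adjusted p = 0.026. All 6 exposed animals lay below every control for both probes. The 2 probes ran close together in most animals, though not in 0.005 µg/L replicate 5 (3.91 for HAZ00850_1 and 0.04 for HAZ04125_1). They need not be 2 separate changes. HAZ17902_1 was chosen after its values were seen, as the only probe called by the F test among the 5 groups of stage IV animals. It fell by 2.00 ± 0.30 (SE, limma adjusted p = 0.00145), with all 6 exposed animals below every control. It stayed past the threshold in all 18 processing alternatives (limma adjusted p = 0.000872 to 0.0383), of which Aquantile leaves log ratios as they are. It also passed in all 12 fits without 1 of the animals compared. The fit without 0.05 µg/L replicate 1 is counted in both sets. All 10 probes were also called lower at 0.26 µg/L, and none of the 10 passed the threshold between 0.05 and 0.26 µg/L, which does not show that they were alike. HAZ17835_1, not well above background in any animal at 0.26 µg/L, was a further -2.39 (limma adjusted p = 0.102) there. HAZ08103_1 was a further -1.25 (limma adjusted p = 0.705) at 0.26 µg/L. HAZ00850_1 stood at -4.48 ± 0.86 (SE) and HAZ04125_1 at -4.21 ± 0.78 (SE) against control at 0.26 µg/L. HAZ17835_1 and HAZ08103_1, named above, also fell at 0.05 µg/L (HAZ17835_1 well above background in 4 of 6 animals), by 3.57 ± 0.72 and 4.07 ± 0.78 (SE), with limma adjusted p = 0.0337 and 0.0275.

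In the 12 fits without 1 of the animals compared, chosen for these probes after the data were examined, differences of the 10 probes were 77.4% to 115% of those with all animals. HAZ17902_1 passed the threshold in all 12 fits (adjusted p up to 0.0094), and each of the other 9 in at most 6 of them. HAZ00850_1 was between -4.61 and -4.23 and HAZ04125_1 between -4.52 and -4.09, with adjusted p up to 0.113. The count was 1, HAZ17902_1, when control replicate 2, 3 or 5 or 0.05 µg/L replicate 1, 5 or 6 was left out, 3 without control replicate 6 and 5 without control replicate 1. It was 16 without 0.05 µg/L replicate 3 and 18 without replicate 4. With position in the model it was 3, with slide as a random block 6, with scan day as a random block 13 and with scan day as a fixed factor 1. Over the processing alternatives, these models included, HAZ00850_1 was between -4.64 and -3.97 (limma adjusted p up to 0.113). HAZ04125_1 was between -4.70 and -3.64 (limma adjusted p up to 0.163). On the 3 scan days that held both groups all 10 probes were lower in the exposed animals, with median differences of -2.78, -1.80 and -2.83. All 10 were lower as well within the top arrays and within the bottom arrays. The 10 probes were picked on these same arrays. Fits without 1 of the 3 scan days called 0, 2 and 7 probes, and the 2 and the 7 all kept their direction on the day left out. The scanner software's processed ratios gave 16 probes, 5 of them higher.

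**Figure D3:**
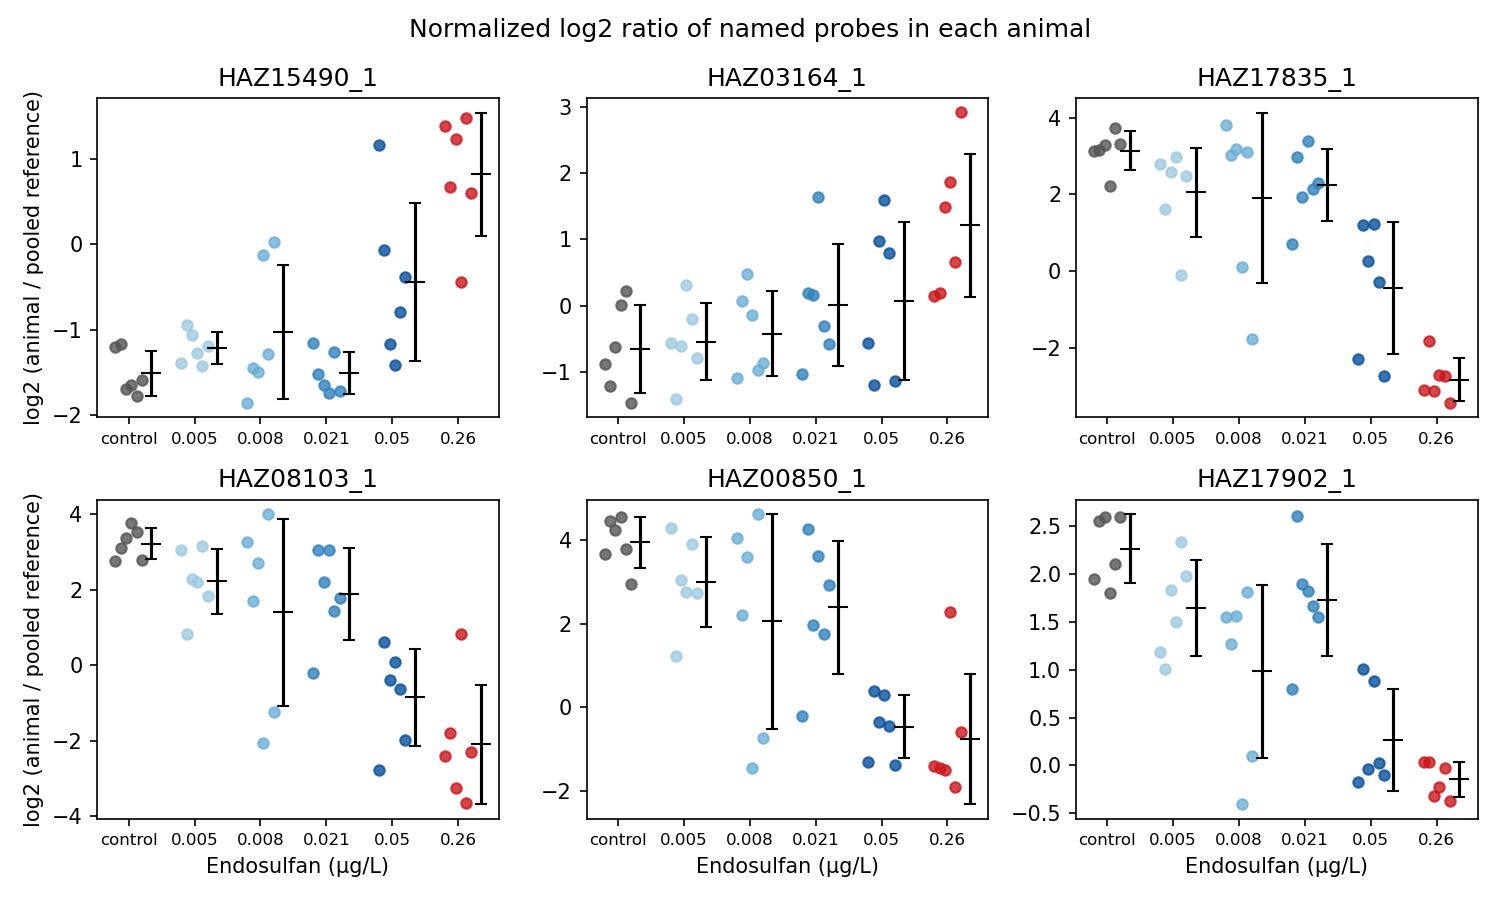
Normalized log2 ratio of animal over pooled reference (y axis) of 6 named probes at each endosulfan concentration (x axis, µg/L; control at left); points are the 6 animals of a group and the bar beside them is mean ± SD. HAZ00850_1 lies between -1.37 and 0.39 in the 6 animals at 0.05 µg/L and between 2.95 and 4.55 in the 6 controls.

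No probe was called at the 3 lowest concentrations in the limma fit. At an unadjusted p under 0.05 there were 341 probes at 0.005 µg/L, 345 at 0.008 µg/L and 250 at 0.021 µg/L, against 609.7 expected by chance among 12194 independent probes. The smallest adjusted p was 0.998 or more in all 3 comparisons. At 0.05 and 0.26 µg/L there were 676 and 1410 probes at an unadjusted p under 0.05. Of the 10 probes lower at 0.05 µg/L, all 10 had mean values below control at each of the 3 lowest concentrations too, with median differences of -0.76, -1.17 and -0.73. Those probes were picked for low values against the same controls, so part of these differences comes from the shared control animals. Spread between animals was wide at 0.008 µg/L, where replicates 4 and 6 held the low values of these 2 probes. HAZ08103_1 was -2.05 and -1.23 in them and 1.70 to 4.00 in the rest of the group, against 2.76 to 3.76 in controls. HAZ00850_1 was -1.44 and -0.73 in them and 2.22 to 4.62 in the rest.

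Across the 6 groups 305 probes differed by the moderated F test. Without 0.26 µg/L replicate 5 or 6 the count was 186 or 194, with median centring 64 and with Cy3 alone 61. Among the 5 groups of stage IV animals 1 probe differed, HAZ17902_1 (limma adjusted p = 0.0169), with 369 probes at an unadjusted p under 0.05. Its group means were 2.27 ± 0.36 in controls, 1.64 ± 0.50, 0.98 ± 0.91, 1.72 ± 0.58 and 0.27 ± 0.53 with rising concentration, and -0.14 ± 0.18 at 0.26 µg/L (SD, n = 6 each). It did not pass the threshold when control replicate 2, 3 or 6 or 0.05 µg/L replicate 1, 3, 5 or 6 was left out, where the count was 0. No probe had a trend over the rank of concentration in stage IV animals (smallest limma adjusted p = 0.0693), with 746 probes at an unadjusted p under 0.05. With concentration in µg/L in place of its rank the count was 15. Single animals moved the count of trends as well: it was 12 without 0.021 µg/L replicate 4, 6 without 0.021 µg/L replicate 2, 4 without 0.008 µg/L replicate 4, 2 without 0.005 µg/L replicate 2 or 0.008 µg/L replicate 5 or 6, and 1 without 0.05 µg/L replicate 2.

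Changes at 0.05 and 0.26 µg/L were compared over all 12194 probes. Their log2 differences from control correlated at r = 0.67, where 100 simulations of unchanged groups against the same controls had a median of 0.50 and reached 0.82. The covariance was 0.0355 against a mean of 0.00880 and a highest value of 0.0244 in the simulations. With control replicates 1 to 3 for one comparison and 4 to 6 for the other, r was 0.42 and 0.45, against a median of -0.03 and a highest value of 0.49 without any change. All 10 probes called lower at 0.05 µg/L were among the 215 called lower at 0.26 µg/L. Independent lists would share 0.176, a value that leaves out the shared controls. In 100 simulations of unchanged groups against the same controls, added after the data were examined, the 10 falls of smallest p at 0.05 µg/L and the 215 at 0.26 µg/L shared a median of 4 and at most 9. With split controls these lists shared 7 and 8, against a median of 0 and at most 8 and 3 in the simulations. In the other 9 pairs of concentrations the covariance stayed below the highest simulated value. All these simulations left both groups unchanged, although 453 probes differed at 0.26 µg/L. They do not give the values for an unchanged 0.05 µg/L group beside a changed 0.26 µg/L group. Values beyond them thus do not by themselves show shared changes. Of the 453 probes called at 0.26 µg/L, 425 had the same direction at 0.05 µg/L, with a median of 0.22 in that direction, which is 34.9% of the median at 0.26 µg/L. The numbers were 333, 378 and 300 of 453 at 0.005, 0.008 and 0.021 µg/L, with medians of 0.07, 0.11 and 0.04. These shares include the chance values of the shared controls.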

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

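These checks ran over 66 sets of 6 animals, where chance alone gives about 3.3 with 1 animal far from the rest, and 3 were found. HAZ00850_1 was 2.29 on the log2 scale in 0.26 µg/L replicate 4, and -1.90 to -0.60 in the other 5 animals of that group. In the same animal HAZ04125_1 was 2.30, against -1.44 to -0.37 in the other 5. These 2 probes ran close together in most animals, so the 2 finds in this animal need not be separate. Among controls, HAZ04125_1 was 2.18 in replicate 6 and 3.57 to 4.37 in the others. Without 0.26 µg/L replicate 4 the count of probes called at that concentration was 551, and without control replicate 6 it was 337, of the 453 with all animals.

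Chance as the origin of the counts was tested with 100 splits of the same arrays, the real one included. For 0.26 µg/L against control 1 split, the real one, gave as many as 453 probes, and the highest other gave 181, after 1 animal of each group had changed places. For 0.05 µg/L 1 split, the real one, gave as many as 10, and the highest other gave 1. The same held for the 305 probes across 6 groups (highest other 63) and the 709 of 0.26 µg/L against the stage IV groups (highest other 10). For these 4 counts chance is thus unlikely but not excluded, since 100 splits cannot show a share below the real one alone. Of the splits of the stage IV arrays, 2 gave as many as the 1 probe found, with a highest other of 1, so another split matched the real count although their share was small, and the call was lost in 7 of 30 fits without 1 array. For the comparisons of 0.005, 0.008 and 0.021 µg/L and for the trend the splits tested nothing: with 0 probes found, all 100 give at least as many by construction. The highest others were 1, 1, 6 and 76.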

How the results depend on the processing

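Scan day as a fixed factor, arrays of 1 position and the fit without 0.05 µg/L replicate 1, the array least like the others, were chosen after seeing the data. The cause of a change was not tested except where named. The counts at 0.005 and 0.021 µg/L stayed at 0 in all 20 alternatives and all 36 fits without 1 array. At 0.008 µg/L adjustment over all 5 comparisons together gave 1, and 0 to 0 without single arrays. The same adjustment gave 23 at 0.05 and 254 at 0.26 µg/L, because the comparisons then share one threshold. At 0.05 µg/L (main 10) the processed ratios gave 16, Cy3 alone 6, the filter on all 36 arrays 5, slide block 6, position 3, the trend and robust prior 1, scan day fixed 1 and the fit without replicate 1 also 1, with 1 to 18 without single arrays. At 0.26 µg/L (main 453) median centring gave 91, Cy3 alone 115, top arrays 109 and bottom arrays, with 1 control, 0. Without single arrays it was 308 to 551. Across 6 groups (main 305) these were 64 with median centring, 61 with Cy3 alone and 469 with scan day fixed, and 186 to 384 without single arrays. Among stage IV groups (main 1) the count was 0 with median centring, Cy3 alone, the trend and robust prior, scan day fixed and without 0.05 µg/L replicate 1, and 0 to 1 without single arrays. The trend (main 0) gave 1 with median centring, 1 with scale normalization, 1 with Cy3 alone, 2 with the filter on all arrays, 2 with array weights and 15 in µg/L, and 0 to 12 without single arrays. Against the stage IV mean (main 709) median centring gave 180 and Cy3 alone 190, with 450 to 781 without single arrays. The correlation of changes at 0.05 and 0.26 µg/L (main 0.67) was 0.42 and 0.45 with split controls, by construction, and 0.59 to 0.71 without single arrays. No named probe changed direction in any alternative. Aquantile leaves log ratios as they are and tests nothing.

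Replicate numbers were not treated as pairs, and whether same-numbered animals share something stays open. Same-numbered deviations correlated from -0.40 to 0.45, with 45 of 90 pairs at 0.1 or below. All 15 pairs of number 1 lay between 0.07 and 0.44, with a median of 0.23, and number 4 had a median of 0.20. Medians were -0.02, -0.07 and -0.04 for numbers 2, 3 and 5, and 0.11 for number 6. Of 36 arrays, 5 correlated best with an array of their own number. As a replicate block the number gave 5 probes at 0.05 µg/L and 455 at 0.26 µg/L. Gene list tests and their alternatives, and 1 probe per gene name, were not run because no probe could be named. Dim spots limit the depth: 2398 probes were too dim to test, and 4 probes called lower at 0.26 µg/L have only a bound there.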

Other observations

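The tests of position at 0.26 µg/L, of the profile at 0.05 µg/L and of the exposure group in the covarying probes were chosen after the results they bear on were seen.

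The 453 probes that differed at 0.26 µg/L were set against layout and stage. With position on the slide in the model 346 probes remained past the threshold, above the 118 of the highest of the other 99 splits fitted with position too, which argues against position as the whole origin. In a test of scan day fixed before its result was seen, probes called without one scan day were read on that day. At the lowest of the 3 days 89.2% kept their direction, which argues against scan day as the whole origin. Each of these days held 1 animal at 0.26 µg/L and 1 or 2 controls, and probes are not independent. The percentages thus rest on 3 comparisons of few animals. Larval stage stays open: 0 arrays hold a stage IV animal at 0.26 µg/L or a stage III animal at another concentration, so a direct effect of endosulfan cannot be told apart from a difference between stages, or from a delayed moult to stage IV.

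Some stage IV animals at 0.05 µg/L shared part of the profile of the stage III animals at 0.26 µg/L. Each animal in turn was left out, the probes that differed between the 0.26 µg/L group and the mean of the other groups were found from the remaining 35 arrays, and the mean log2 ratio of falling probes was subtracted from that of rising probes in the left-out animal. This score was -0.09 ± 0.10 in controls, -0.04 ± 0.09 at 0.005, 0.09 ± 0.40 at 0.008, -0.08 ± 0.12 at 0.021, 0.33 ± 0.33 at 0.05 and 1.27 ± 0.47 at 0.26 µg/L (SD, n = 6 each). At 0.05 µg/L it was 0.42 above control, 30.7% of the gap between control and 0.26 µg/L, and all 6 animals lay above every control, whose highest score was 0.02 (two-sided exact permutation p = 0.00216, the smallest possible; 0.0054 adjusted over 5 comparisons). The animals were far from alike: replicates 1 and 6 scored 0.74 and 0.75, and replicates 2 to 5 scored 0.15, 0.23, 0.04 and 0.07. At 0.008 µg/L replicates 4 and 6 scored 0.56 and 0.62 and the other 4 animals -0.28 to -0.02. At 0.26 µg/L replicate 4 scored 0.50, below those 2 animals and below replicates 1 and 6 at 0.05 µg/L. The rest of the 0.26 µg/L group scored 1.00 to 1.81. Lists of rising probes held 226 to 397 probes for animals at 0.26 µg/L and 319 to 327 for controls, so the gap compares unlike lists. The mean at 0.05 µg/L thus rests largely on single animals and does not show an even shift of all. The difference was 0.31 to 0.69 over 11 alternatives, with exact permutation p of 0.013 or less. These alternatives changed the values, probes or arrays used. None of them put position, slide, scan day or replicate number in the model. Aquantile, among them, leaves log ratios as they are and tests nothing. At 0.005, 0.008 and 0.021 µg/L the adjusted exact permutation p was 0.5, 0.5 and 0.831. The slope over the 5 stage IV groups was 0.08 per step of rank (two-sided permutation p = 0.0208), and 0.02 without the 0.05 µg/L group (permutation p = 0.674), so it rests on that group.

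Rising probes were 0.14 higher and falling probes were at -0.28 against control at 0.05 µg/L (exact permutation p = 0.0173 and 0.0238). Loess centres the ratios of each array, so these values do not test a general loss of ratio. Within scan days that held both groups the score differed by 0.39, 0.25 and 0.40. Position stays open: the difference was 0.16, or 38.0% of the pooled one, among top arrays with 2 exposed animals and 5 controls, and 0.47 among bottom arrays with 4 exposed animals and 1 control. A candidate explanation is that 0.05 µg/L held back part of the change that accompanies the passage to stage IV, more in some animals than in others. This was not tested. The scores did not rise step by step with concentration: replicates 4 and 6 at 0.008 µg/L scored 0.56 and 0.62, while the mean at 0.021 µg/L was -0.08. A part of the high scores that does not depend on concentration is therefore not excluded. The time since the moult was not analysed here and would separate a delay from a direct effect on the same probes.

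Most of the most variable probes changed together. Of the 60 probes with the largest SD within groups, 44 formed 1 block in which pairs correlated across arrays with a median r of 0.91 after group means were removed. Their SDs within groups were 1.01 to 1.98, against a median of 0.181 over all tested probes. The mean of the block ranged from -1.49 to 2.57 between animals, a span of 4.06 on the log2 scale. Every group but 0.26 µg/L held animals both below and above 0: controls ran from -1.49 to 2.57, 0.05 µg/L from -0.68 to 2.57 and 0.26 µg/L from 0.34 to 2.00. Of the 44 probes, 34 were well above background on all 36 arrays and 1 was among the called probes of the comparisons above. HAZ03164_1, called higher at 0.26 µg/L, is not among the 44, but among controls it ran alongside the block. It was -1.46 and -1.22 in control replicates 6 and 2, where the block mean was -1.49 and -1.43. In replicates 5 and 4 it was 0.22 and 0.02, where the block mean was 1.97 and 2.57. Whether its rise reflects the block was not tested.

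The choice of these probes by their spread within groups lowers the share of variance between groups, so exposure was tested on a block found from the spread over all arrays, with no group means removed. It held 36 probes, all of them among the 44. The 6 groups accounted for 10.3% of the variance of its mean, where permuted labels had a median of 12.8% (permutation p = 0.631). Controls alone ran from -1.64 to 2.71, the whole range of the 36 arrays, which argues against exposure as the whole source. A smaller contribution of exposure is not excluded. Brightness of the array is argued against: Pearson r with the number of probes well above background in Cy3 was 0.10 (permutation p = 0.552) and Spearman rho -0.01 (permutation p = 0.942) over 36 arrays, and r was 0.11 without the 2 arrays farthest from the median. Scan days accounted for 45.3% of the variance, where permuted days had a median of 21.8%. The permutation p was 0.0202, or 0.081 adjusted over the 4 factors tried, so a batch may contribute. Those factors were scan day, group, slide and position, and replicate number was not tried. The mean of the 44 probes ran from 1.25 to 2.57 in animals numbered 4 and from 0.60 to 2.48 in those numbered 3. It ran from -1.36 to 0.78 in animals numbered 1, and numbers 2, 5 and 6 also held animals on both sides of 0. Whether the block follows replicate number stays open. A state of the animals that differs between individuals of one stage, such as the phase of the moult cycle or recent feeding, is another possibility that these labels leave untested.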
